A study of Mus musculus with 2 samples.

How the data were processed

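DNase-seq measures accessible chromatin: nuclei are treated briefly with DNase I, the released ends are sequenced, and dense cuts mark open DNA. The data were 2 libraries of frontal cortex from male B6CASTF1/J mice aged 14 days, numbered as biological replicates 1 and 2 per the labels, each labelled as tissue of 3 males, with separate tissue samples and 1 shared donor number. Both formed 1 group, and there was nothing to compare it with.

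The authors deposited, per library and not pooled, peak lists, footprints and a track of cut rates, all in assembly mm10 per the deposited file descriptions. The aligner, the peak caller, the footprint caller and their versions were not given in the sources used here. The height of each peak is the authors' deposited signal value, scaled per library on a scale that was not stated. Every height was a whole multiple (within 0.05 steps) of 1 fixed step, 0.0119 in replicate 1 and 0.00834 in replicate 2. The deposited cut rate track gives a false discovery rate, a p-value or q-value kind of unit, for runs of bases, and it listed bases below 0.05, 22.3 Mb in replicate 1 and 24.8 Mb in replicate 2. The deposited footprints carry the constant 0.01 in their p-value or q-value column, read here as the calling threshold, so no footprint had a strength of its own. Each library had 2 deposited peak lists. All peaks of the longer list held a base with a false discovery rate below 0.05, and all peaks of the shorter list one below 0.001, tested on every peak against the cut rate track. The longer list was used throughout, and the shorter one as an alternative. Because heights were scaled per library and the calling steps are unknown, a height was used to describe and rank peaks within a library, between libraries for correlations and ratios that say so, and as a mean of both libraries to rank genes by promoter height. These means combine 2 scales that were set per library. Reads of an F1 hybrid that map to the reference of 1 parent strain less well at variants of the other could lower single heights, which was not tested.

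Total read counts were not used here, so no counting interval could be given. The step of replicate 1 was 1.43 times that of replicate 2, and the precision of each value is given by the gap between the 2 libraries. Values are given per library or as mean ± SD with n = 2. There was no test between groups, and ranks among random lists are descriptions without a p-value.

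Peaks were called shared when they overlapped by at least 1 bp, and overlapping peaks of both libraries were joined into shared regions with the highest height of each library. Chance overlap came from 100 seeded random shifts of all peaks along their chromosomes. A promoter was the 1000 bp on both sides of any annotated start site of a protein-coding gene in GENCODE M21 (21938 genes, 93513 start sites), and a promoter height was that of the highest peak there, which can be a different peak in each library; the 2 heights are then given without a mean. Distal regions were shared regions farther from every such site, counted over the gene's span plus 10 kb on both sides and divided by that length in units of 10 kb. Annotation and genome sequence were of mm10, the files' own assembly. For 22 gene lists with 276 different genes, the share of genes with a promoter peak in both libraries was ranked among 10000 random lists of the same size matched on decile of promoter GC content, and the median distal density among 10000 random lists matched on decile of gene length. A list was said to stand apart beyond percentiles 97.5 and 2.5. On simulated promoter status over 21938 genes, 3 in 100 lists of 12 genes without an effect passed these limits, and 81.5% of lists raised by up to 40 percentage points were found. The matching groups were drawn at random, not from promoter GC content, and each gene's status was drawn independently. The simulation therefore did not test the real GC deciles or lists of neighbouring genes.

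Footprint sharing used 1 bp of overlap, with chance given by 100 random re-placements of each footprint inside its own peak. Motif content was the number of matches to 23 fixed consensus sequences on either strand whose middle base lay in a footprint, per base, over the same density in the rest of the peaks, beside the reversed sequence. A ratio was given where the rest of the peaks held at least 10 matches. A quotient of this ratio and that of the reversed sequence was computed first and dropped after its values were seen, because it was not finite where the reversed sequence had too few matches, in favour of the ratio fixed beforehand.

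The gene lists, consensus sequences, main comparisons, most alternatives and the rule for named genes were fixed before the data were examined. Several tests of explanations were chosen after the results were seen, as said where they are given. The rule took, per list, the 2 genes with the tallest promoter peaks, the 2 with the lowest, up to 2 without one, and the gene with the most distal regions per 10 kb. Over all genes it took the 10 tallest promoters and the 10 genes with most distal regions, and per library the 3 tallest peaks called in that library alone. Counts of 5 or fewer were to be named in full. Some genes that this rule takes are not reported here. Alternatives covered the shorter peak list, peaks above the median height, overlap of 50% of both peaks, promoter windows of 500 and 2000 bp, 1 start site per gene, unmatched lists, 50 kb flanks, a footprint background of 50 bp on both sides, and leaving out each library. A distal definition that excludes start sites of all annotated genes and a promoter definition that asks for 1 shared region were added after seeing the data. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.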

Results

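Accessible DNA was mapped by DNase-seq in the frontal cortex of male mice aged 14 days, bred as the F1 hybrid B6CASTF1/J of a laboratory strain and a wild-derived strain. DNase I cuts DNA more readily where it is not wrapped in nucleosomes, so that dense cuts mark open promoters and enhancers. Short gaps in the cuts inside an open region (footprints) are read as bases that a bound protein may cover. The 1 group held 2 libraries, replicate 1 and replicate 2, each labelled as tissue of 3 males. The labels give the libraries separate tissue samples but the same donor number, so the spread between them may be partly technical. With 1 group there was no contrast between conditions, and no p-values were computed. Read depth was not given in the sources used here, and each library had its own smallest step of peak height, 1.43 times as large in replicate 1 as in replicate 2. All coordinates are 1-based positions in the mouse assembly mm10, and peak heights are the authors' own values on a scale set per library.

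The tallest promoter peak in the mean of both libraries lay at Dynlt1b, a light chain gene of the dynein motor, with heights of 34.6 and 26.8 (mean 30.7 ± 5.51, SD, n = 2). Dnpep, an aminopeptidase gene, stood at 23.9 ± 0.605 (SD, n = 2). Tle4, a corepressor gene used as a marker of deep-layer corticothalamic neurons, came next at 23.6 ± 2.02 (SD, n = 2). Its peak lay on chromosome 19 within 14598221 to 14598500, upstream of the annotated gene (14448150 to 14598051, minus strand). Ankhd1, Hjurp, Trpm8, Rab11b, Ppm1b and Zfp143 were also among the 10 tallest, between 22.8 and 21.2. Hjurp and Trpm8 share 1 peak that covers the start sites of both, so its height of 22.5 ± 1.91 (SD, n = 2) cannot be assigned to either gene.

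Replicate 1 held 75753 peaks covering 15.1 Mb, with a median width of 200 bp and a median height of 0.848. Replicate 2 held 77035 peaks covering 16.6 Mb, with a median width of 207 bp and a median height of 0.801. Of these, 73.3% in replicate 1 and 71.7% in replicate 2 overlapped a peak of the other library by at least 1 bp, against 1.2% on average after 100 random shifts of the peaks along their chromosomes. The overlapping peaks formed 53623 shared regions. Taller peaks were shared more often: in the lowest decile of heights the shares were 31.0% and 26.6%, and in the highest decile both were 99.6%. Across the shared regions, which are not independent replicates, the heights correlated with Spearman's rho 0.919 and with Pearson's r 0.950 on the log2 scale. The median log2 ratio of replicate 2 over replicate 1 was -0.06, the central 95% of regions lay between -0.89 and 0.59, and 1.35% of regions stood more than 2-fold from the median ratio.

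**Figure D1:**
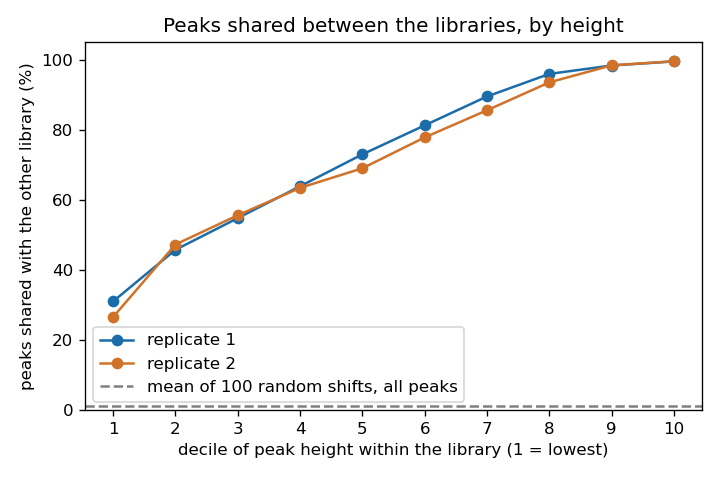
Share of peaks that overlap a peak of the other library (y axis, percent) by decile of peak height within the library (x axis, 1 lowest), 1 line per library, with the mean of 100 random shifts as a dashed line. The shares run from 31.0% and 26.6% in the lowest decile to 99.6% in the highest, while random shifts give 1.2%.

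The peaks called in 1 library alone numbered 20197 in replicate 1 and 21790 in replicate 2, with median heights of 0.537 and 0.50. The tallest of replicate 1 lay at the zinc finger gene Zfp446 (chromosome 7, 12977701 to 12977960, height 6.91), at Nudt6 (chromosome 3, 37419501 to 37419740, height 5.47) and 77 bp from Pip4k2b (chromosome 11, 97744781 to 97745000, height 4.91). The tallest of replicate 2 lay 243 bp from Sp1, a gene for a GC-box binding factor (chromosome 15, 102405541 to 102405900, height 12.3), 581 bp from Zbtb20 (chromosome 16, 42875001 to 42875300, height 7.78), and far from any protein-coding gene, 224193 bp from Pcmtd1 (chromosome 1, 7397821 to 7398020, height 6.86). At all 6 sites the other library also listed bases, with smallest false discovery rates from 1.72e-29 at Pip4k2b to 8.23e-88 at Zbtb20. At Zfp446, Nudt6, Pip4k2b and Zbtb20 these were lower than in the library that called the peak, and at Sp1 and Pcmtd1 higher. A peak of the other library ended or began at most 100 bp away from each site.

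Open regions were concentrated at promoters. Of the shared regions, 35.5% lay within 1000 bp of an annotated transcription start site of a protein-coding gene, against 4.36% on average under random shifts. A further 29.0% lay inside protein-coding genes away from promoters, and 35.5% lay outside them. Promoter peaks were taller than distal peaks in both libraries, with median heights of 1.33 against 0.752 in replicate 1 and 1.2 against 0.692 in replicate 2. The ratios of 1.76 and 1.73 differed far less between the libraries than either differed from 1. Of 21938 protein-coding genes, 13090 (59.7%) had a promoter peak in both libraries and 915 in 1 library alone. For 662 of the former the tallest peaks of the libraries lay at different sites of the promoter windows, and 13041 genes had 1 region shared by both libraries there. GC-rich promoters were open most often: the share with a peak ran from 4.51% in the lowest decile of promoter GC content to 85.3% in the highest. Lists of genes were for this reason compared with random lists matched on promoter GC content.

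Genes of excitatory cortical neurons had open promoters. Of 14 markers of excitatory neurons, 13 had a promoter peak in both libraries, a share at percentile 98.9 of 10000 matched random lists. Camk2a, a kinase gene of the postsynaptic density, had the tallest, 3.51 ± 0.049 (SD, n = 2), on chromosome 18 (60925441 to 60925680 in replicate 1). Emx1, at 1.00 ± 0.051 (SD, n = 2), and Slc17a6, the vesicular glutamate transporter gene that dominates in the thalamus and brain stem, at 0.644 ± 0.151 (SD, n = 2), were lowest. Slc17a7, the cortical vesicular glutamate transporter gene, had a promoter peak in replicate 2 alone (height 1.18, at 45169633 to 45169761 inside the gene on chromosome 7), while a shared region upstream of the gene and outside the promoter window (45161961 to 45162500) had heights of 4.19 and 4.36. Of 14 cortical layer genes, 13 had a promoter peak in both libraries (percentile 98.2), led by Tle4 and by the upper-layer factor gene Pou3f3 at 9.46 ± 0.311 (SD, n = 2), with Ldb2 (1.13 ± 0.179, SD, n = 2) and Sox5 (0.860 and 0.809, at different sites in the libraries) lowest. Fezf2, a determinant of subcerebral projection neurons, had none in either library. With replicate 2 alone the cortical layer list fell to percentile 96.9, just inside the limit of 97.5, with replicate 1 alone it stood at the limit, and with a window of 2000 bp at 97.4. With a window of 500 bp the excitatory list fell to 95.7, also inside the limit.

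All 14 synaptic and pan-neuronal genes had a promoter peak in both libraries (percentile 100). Homer1, a postsynaptic scaffold gene, stood at 7.03 ± 0.387 (SD, n = 2) and Dlg4, the gene of the scaffold PSD-95, at 5.58 ± 0.195 (SD, n = 2), while Rbfox3, the gene of the neuronal marker NeuN, stood at 1.46 and 1.38 and the adhesion gene Nlgn1 at 1.22 and 1.09, both at different sites in the libraries. All 14 immediate early genes, which are switched on by neuronal activity, also had one. Among random lists matched on their GC-rich promoters this stood at percentile 97.1, inside the limit. No higher percentile was possible there, since the share was already full and random lists with a full share counted as ties. The matched rank therefore cannot decide whether these promoters stand apart. The list lay beyond the limit with a window of 500 bp (98.0), with peaks above the median height (99.1) and with unmatched lists (99.96). Jun reached 17.4 ± 1.46 (SD, n = 2) and Egr1 7.60 ± 0.765 (SD, n = 2), whereas Bdnf (1.24 ± 0.166, SD, n = 2) and Nr4a2 (1.52 and 0.942, at different sites) were lowest. The 14 housekeeping genes (percentile 99.7), led by Rpl13a at 13.3 ± 0.512 and Ywhaz at 9.17 ± 0.338 (SD, n = 2), and the 12 genes of DNA methylation and chromatin architecture (percentile 99.8) were open throughout. Of the last list, the cohesin gene Smc3 stood at 9.10 ± 0.069, while Dnmt3a (1.62 ± 0.157; SD, n = 2) and Arid1b (1.58 and 1.72, at different sites) were lowest.

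Genes of GABAergic interneurons did not stand apart by their promoters. Of 14, 10 had a promoter peak in both libraries (percentile 54.6), with Dlx6 at 2.14 ± 0.316 and Adarb2 at 2.05 ± 0.278 highest (SD, n = 2) and Pvalb (0.908 and 0.534) and Npy (0.370 and 0.434) lowest, each at different sites in the libraries. Lhx6, Sst and Vip had none, and Dlx1 had one in replicate 1 alone (height 1.33). Astrocyte genes (8 of 12, percentile 56.7) ranged from the glutamine synthetase gene Glul at 5.72 ± 0.088 and Sox9 at 3.67 ± 0.006 (SD, n = 2) down to Gfap at 0.974 ± 0.092 (SD, n = 2) and the connexin gene Gja1 at 0.908 and 0.509 (different sites), while the water channel gene Aqp4 and Fgfr3 had none. Oligodendrocyte precursor genes (7 of 10, percentile 30.8, and 54.2 with replicate 1 alone) were led by Olig1 at 2.28 ± 0.023 (SD, n = 2), and Cspg4, the gene of the precursor marker NG2, and Nkx2-2 had none. Of 12 microglial genes, 6 had a promoter peak in both libraries (percentile 13.0, and 46.7 with replicate 2 alone), among them Sall1 at 1.53 ± 0.045 (SD, n = 2), and the growth factor receptor gene Csf1r had none. Striatal genes (8 of 10, percentile 53.2), with Rgs9 at 3.58 ± 0.060 (SD, n = 2), and genes of neural progenitors and proliferation (9 of 12, percentile 32.6), with the topoisomerase gene Top2a at 5.84 ± 0.463 (SD, n = 2), also lay inside the limits. Drd2 was the striatal gene without a peak in either library, and Nes and Eomes were those among the progenitor genes.

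Promoters of myelin genes, of Hox genes, of genes of thalamus, midbrain and hindbrain, and of choroid plexus and ependymal genes had a called peak in both libraries less often than those of matched random lists. The libraries are of tissue without separation of cell types, and a promoter without a called peak may still lie under the calling limit. Of 12 genes of myelinating oligodendrocytes, Cnp (1.11 ± 0.056, SD, n = 2) and Mal (0.424 ± 0.127, SD, n = 2) had a promoter peak in both libraries (percentile 0.10), Ermn and Ugt8a had one in replicate 2 alone, and 8, among them Mag and Cldn11, had none. None of 18 Hox genes, which pattern the body axis behind the forebrain, had a promoter peak in both libraries (percentile 0.00), although Hoxa10 and Hoxd11 had one in replicate 2 (0.592 and 0.242) and Hoxc10 in replicate 1 (0.430). Of 14 genes of thalamus, midbrain and hindbrain, Tcf7l2 (1.33 ± 0.23), Prkcd (1.21 ± 0.086) and Tph2 (0.933 ± 0.036) had one (SD, n = 2; percentile 0.00), and En1 and Barhl1 had none. Of 10 choroid plexus and ependymal genes, Rsph1 (15.0 ± 1.67) and Foxj1 (6.85 ± 0.40), both genes of motile cilia, had one (SD, n = 2; percentile 0.12), and Ttr had one in replicate 1 alone (0.621).

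The same held for lists of organs outside the brain and, less stably, for the vascular list, which is not one of them. Of 12 muscle genes, Pygm (1.45 ± 0.198, SD, n = 2), Actn2, Des, Ckm and Myl2 had a promoter peak in both libraries (percentile 0.64, but 11.7 among unmatched lists). The count was 3 of 12 for blood (Itga2b and Epor among them; percentile 0.88) and 1 of 12 each for liver (Apob at 0.978 ± 0.12, SD, n = 2; percentile 0.17) and germ cells (Dazl at 1.43 ± 0.107, SD, n = 2; percentile 0.00). It was 0 of 10 for epithelium (percentile 0.00), where the cadherin gene Cdh1 and the claudin gene Cldn4 had no peak. The 12 vascular genes, with Foxc1, Slco1c1, Rgs5 and Flt1 open in both libraries, lay at percentile 1.60, but at 4.58 with replicate 1 alone, at 12.1 with replicate 2 alone, at 3.68 among unmatched lists and at 13.4 with a window of 2000 bp. In all, 5 of the 22 lists lay above percentile 97.5 and 10 below 2.5.

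**Figure D2:**
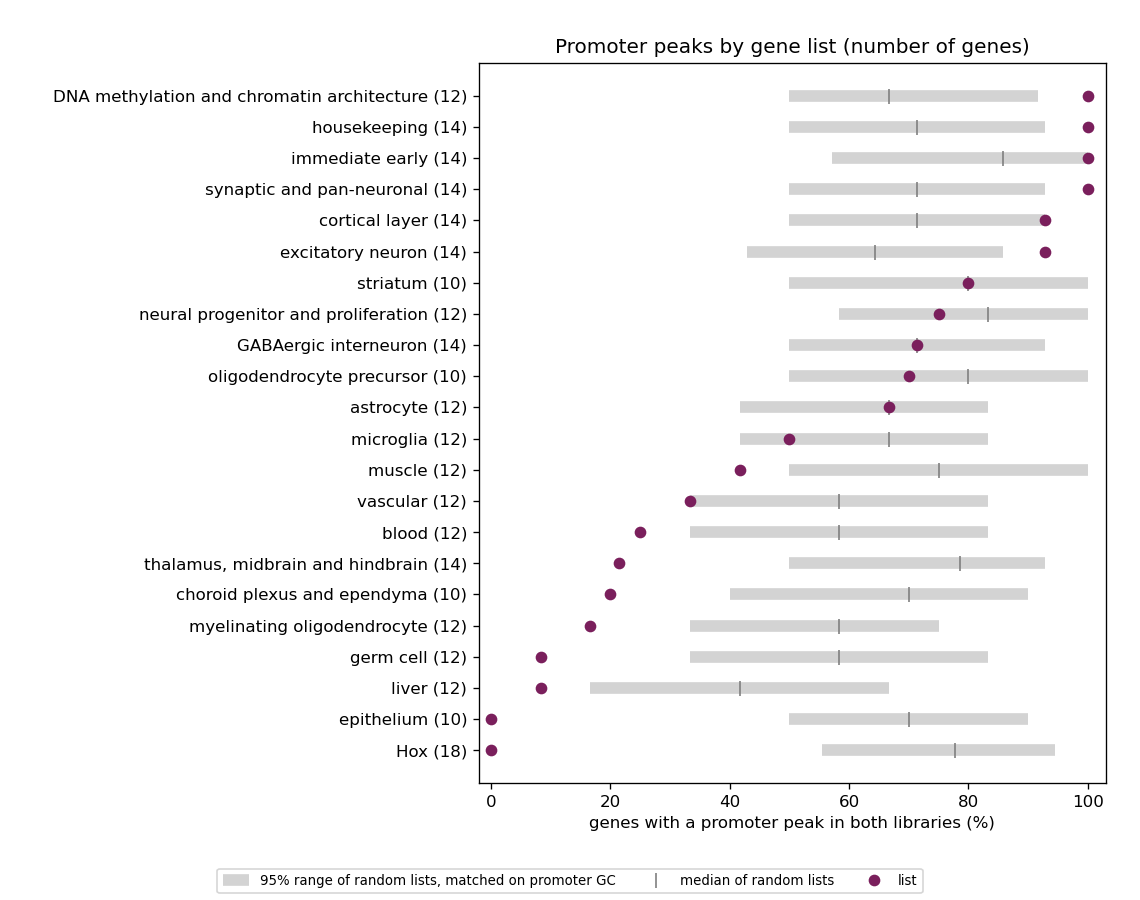
Share of the genes of each list with a promoter peak in both libraries (x axis, percent; points) beside the median (ticks) and the central 95% (grey bars) of 10000 random lists matched on promoter GC content; the number of genes stands in parentheses. Excitatory, cortical layer, synaptic, immediate early and housekeeping lists reach 92.9% to 100%, and the Hox and epithelium lists stand at 0.

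Immediate early genes had a median of 0.759 shared distal regions per 10 kb of gene span and flanks, above all 10000 random lists matched on gene length (percentile 100). Egr1 had 4 such regions, 1.59 per 10 kb. At Fos, a gene chosen for display after its values were seen, shared regions lay at the promoter (chromosome 12, 85473481 to 85473960, heights 2.59 and 2.94), inside the gene near its start (85474421 to 85474776, heights 2.33 and 1.81), upstream (85472021 to 85472309 and 85467821 to 85468280) and downstream (85485901 to 85486240), the last being the tallest with heights of 3.85 and 3.24. Genes of myelinating oligodendrocytes came next with a median of 0.346 per 10 kb (percentile 99.8), in contrast to their promoters. Mbp, the gene of myelin basic protein (chromosome 18, 82475146 to 82585637), held 11 shared distal regions and no promoter peak, the tallest in the mean of both libraries at 82575621 to 82575860 with heights of 2.83 and 2.06.

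**Figure D3:**
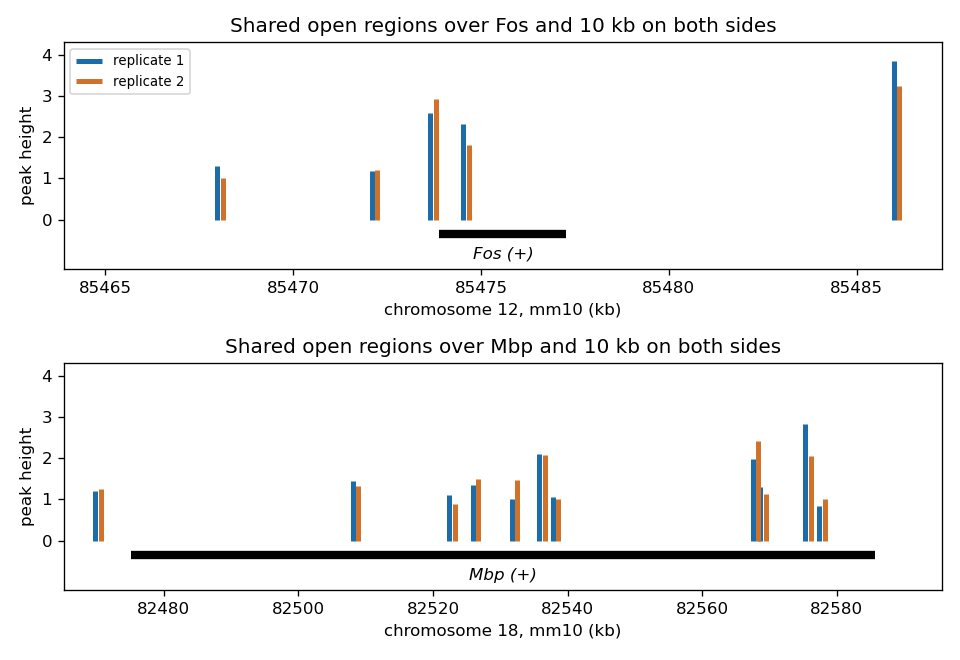
Shared open regions (vertical bars; height in each library on the y axis, in the authors' units) over Fos on chromosome 12 and Mbp on chromosome 18 with 10 kb on both sides (x axis, mm10, kb); black bars are the gene spans. Fos has 5 regions, 2 of them at promoters, and Mbp 11, none of them at a promoter.

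Microglial genes (median 0.340 per 10 kb, percentile 99.2) and astrocyte genes (0.317, percentile 99.0), with 3 at Ntsr2, also lay above the limit. Lists of oligodendrocyte precursors (percentile 97.4, with 7 regions at Cspg4) and GABAergic interneurons (97.1, with 2 at Sst) lay just inside it, and excitatory (91.6), synaptic (92.5) and cortical layer genes (89.0) further inside, although Pou3f3 had 6 regions, 2.19 per 10 kb. The remaining lists ran from Hox at 94.7, thalamus, midbrain and hindbrain at 89.6 and muscle at 81.5 through epithelium at 65.8, striatum at 64.4, blood at 43.4, progenitors at 42.3, liver at 41.0, housekeeping at 41.0 and chromatin architecture at 38.7 to germ cell at 34.8, choroid plexus and ependyma at 32.4 and vascular at 29.4. The order among these lists was not stable: with replicate 1 alone vascular genes stood at 85.4, progenitors at 82.3, liver at 71.6 and chromatin architecture at 60.04, and with replicate 2 alone progenitors at 76.4, chromatin architecture at 67.4, housekeeping at 62.6 and vascular genes at 44.3. The precursor list lay above the limit in all alternatives but the 50 kb flanks, between 97.6 and 99.93. The interneuron list lay above it among unmatched lists (97.53) and with start sites of all genes excluded (98.1). It fell to 90.7 with replicate 1 alone, 85.8 with replicate 2 alone, 72.8 with 50 kb flanks and 47.3 with peaks above the median height. With replicate 2 alone the excitatory list rose to 97.9. A list could not fall below the lower limit where the random lists had a median of 0. With 50 kb flanks the myelin list fell to percentile 91.6 and the microglial list to 96.7, and with replicate 1 alone the microglial list stood at 96.8.

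**Figure D4:**
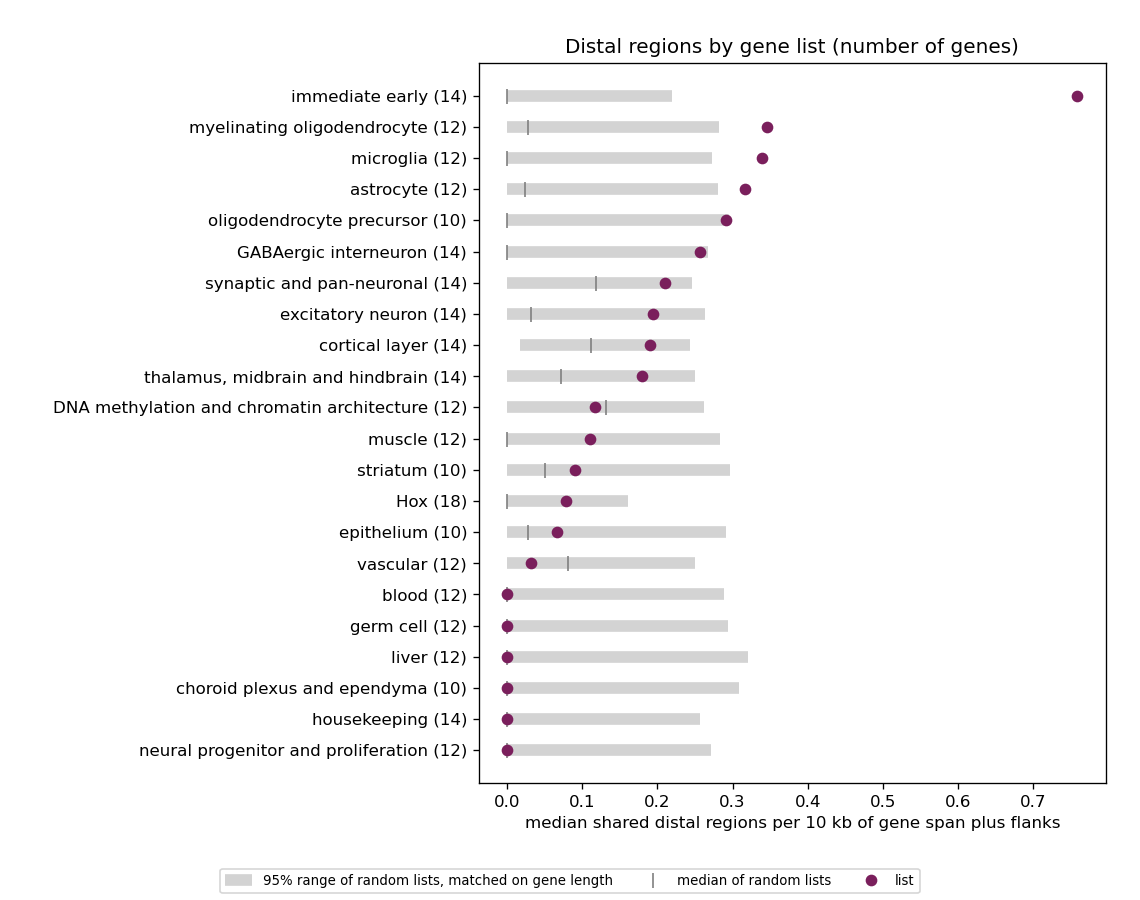
Median number of shared distal regions per 10 kb of gene span plus 10 kb on both sides (x axis; points) for each gene list, beside the median (ticks) and the central 95% (grey bars) of 10000 random lists matched on gene length. Immediate early genes stand at 0.759, beyond every other list, of which myelinating oligodendrocyte genes come nearest with 0.346.

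Over all protein-coding genes, the most shared distal regions lay in Gm20388 (157), Fgfr2 (67) and Gm37240 (36), whose annotated spans run across several neighbouring genes. Long neuronal genes were also among the 10 genes with most: Asic2 (35), Nrxn3 (32), Rbfox1 (32), Auts2 (29), Dlg2 (26) and Kalrn (25).

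Chromosome X carried few open regions. It had 11.3 peaks per Mb in replicate 1 and 11.5 in replicate 2, against autosomal means of 30.2 and 30.7 per Mb over 19 autosomes, a ratio of 0.375 in both libraries. The lowest autosome, chromosome 3, had 23.9 per Mb in both. X-linked genes with a promoter peak in both libraries made up 45.3% of 948, against 60.8% of autosomal genes. The median promoter height on X was 0.586 times the autosomal median in replicate 1 and 0.544 times in replicate 2. Counted as promoter peaks per protein-coding gene the ratio of X to autosomes was 0.755, and with peaks above the median height the ratio per Mb was 0.220. Chromosome Y held 38 and 51 peaks.

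Footprints contained the recognition sequences of general promoter factors and of CTCF. The consensus of NRF1, an activator of nuclear genes for mitochondria (GCGCATGCGC), was 54.0 and 47.2 times as dense in footprints as in the rest of the peaks (mean 50.6 ± 4.87, SD, n = 2). That of CTCF, the insulator protein (CCASYAGRKGGC), was 10.4 times as dense in replicate 1 and 19.5 times in replicate 2, a gap of more than 1.5 times between the libraries. The cAMP response element bound by CREB (TGACGTCA) stood at 13.8 ± 1.98 against 1.04 ± 0.12 for the same bases in reversed order, and the EGR site at 12.7 ± 0.12 against 2.55 ± 0.26 reversed (SD, n = 2). The SP/KLF GC box stood at 13.3 ± 0.627 (SD, n = 2), but its reversed sequence also reached 7.52. RFX (7.32 ± 0.32), NFI (7.06 ± 1.99), YY1 (4.18 ± 1.03) and ETS (2.84 ± 0.050) completed the 9 of 23 sequences with a ratio of at least 2 in both libraries, a limit chosen after the values were seen (SD, n = 2).

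The NeuroD E-box of neuronal differentiation factors stood at 1.86 ± 0.050 against 0.545 reversed, and NFY at 1.60 ± 0.038 against 0.545 reversed (SD, n = 2). The AP-1 site bound by FOS and JUN was less dense in footprints than in the rest of the peaks, at 0.668 ± 0.182 (SD, n = 2), as was its reversed sequence at 0.657. The sites of SOX (0.542), MEF2 (0.606), POU (0.493), LHX/DLX (0.387), SRF (0.663), TBR1 (0.658), ROR (0.418), GATA (0.228), PU.1 (0.498) and HNF4 (0.739) also lay below 1, and HNF1 had no match inside a footprint. Apart from HNF1, the reversed sequences of these sites lay below 1 too, from 0.166 for HNF4 to 0.665 for POU. Only for POU and GATA (0.243 reversed) did the reversed mean exceed that of the consensus. A ratio below 1 was thus not particular to the consensus. Reversing a sequence keeps its base composition but can change its CpG dinucleotides, which are lost for CRE and ETS and gained for SP/KLF, and this limits the control. For CTCF, NRF1, RFX, YY1 and NFI the reversed sequence had fewer than 10 matches in the rest of the peaks of a library and gave no ratio.

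**Figure D5:**
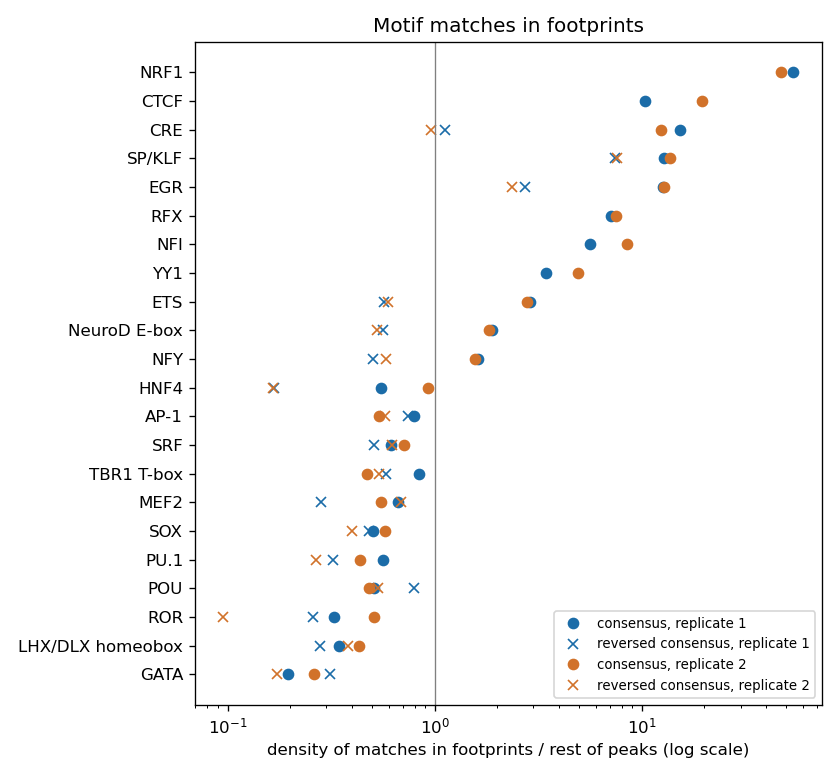
Density of consensus matches in footprints over that in the rest of the peaks (x axis, log scale) for each factor, with circles for the consensus and crosses for the reversed sequence, 1 colour per library. NRF1 stands highest with 54.0 and 47.2 and GATA lowest, and 9 sequences reach 2 in both libraries.

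Replicate 1 had 156390 footprints and replicate 2 had 202779, both with a median width of 10 bp, and 46.7% and 48.1% of them lay at promoters. Of the footprints of replicate 1, 54.8% overlapped one of replicate 2, and 41.3% the other way round. Inside peaks the mean share was 46.6%, against 25.4% after random re-placement of each footprint within its own peak. In the Fos promoter region both libraries had overlapping footprints at 85473796 to 85473812 (GCTTCCCCCCCCTTCCA in replicate 1), a site chosen after its values were seen. Most footprints of either library in this region overlapped none of the other library. A footprint of replicate 2 covered the TATA box (85473857 to 85473870, TATAAAGGCGCCAG), and the one of replicate 1 that overlaps it began inside the box (85473861 to 85473877, AAGGCGCCAGCTGAGGC).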

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

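The tests of closeness to the calling limits, of neighbouring peaks, of tall peaks without listed bases, of the same shared regions and of X peaks per open gene were chosen only after the results they bear on were seen, and the bounds for the top height decile were set with its values in view. The track of false discovery rates was used only to look up its listed bases in peaks and footprints, and 34.6% of the bases it lists in replicate 1 and 35.8% in replicate 2 lay outside every peak of the same library. Of all footprints, 9.92% and 12.6% lay outside peaks, while 99.5% and 99.3% overlapped listed bases.

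Peaks called in 1 library alone were 20197 and 21790. The top height decile held 33 and 28 of them, including the sites at Zfp446 and Sp1. Of these, 97.0% in replicate 1 and 96.4% in replicate 2 had a peak of the other library within 150 bp, and 3.03% and 3.57% had none. Random shifts gave 1.84% and 1.83%, but over peaks of all heights called in 1 library alone. They therefore give no chance level for peaks this tall, and the bounds were set with the values in view. Peak boundaries placed differently stay a candidate explanation there. Sites open in one pool of mice and closed in the other stay undecided there. The labels give 1 shared donor number and do not state whether the libraries come from different mice. That there are separate pools is thus an assumption of this explanation. Among all peaks called in 1 library alone and taller than the median, fewer had a peak of the other library within 150 bp (17.7% and 16.0%). Of all peaks of that height, 6.99% and 8.91% lacked a partner, above the 5% set in advance as speaking for sites open in one pool of mice alone. In the test added after the results were seen, 4.36% and 6.49% lacked listed bases of the other library too, on both sides of the 5% bound. Sites open in one pool of mice alone therefore stay undecided for these peaks. Accessibility near the calling threshold stays open: 19.7% and 13.7% of all peaks called in 1 library alone (37.6% and 27.2% of those taller than the median) held bases listed in the other library, the shares over all of them below the 30% set in advance as speaking against it, but the track ends at the rate that defines the peaks, so a site just short of the limit is not listed. Of all peaks called in 1 library alone, 13.3% and 18.8% reached a rate below 0.001 in their own library with no listed base in the other, between the bounds set for this test.

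Replicate 2 had 1.30 times as many footprints as replicate 1. More or wider peaks in replicate 2 were not the whole cause, since over the same shared regions the ratio was still 1.21; per kb of peak it was 1.154, between the bounds of 1.1 and 1.2 set in advance, which alone decides nothing. At the same height counted in steps of each library's own scale the ratio was 0.989 (95% bootstrap interval over regions 0.984 to 0.995), consistent with more sequencing of replicate 2, if 1 step stands for the same number of cuts in both libraries. No biological explanation was tested for this pattern, as both libraries belong to 1 group.

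Chromosome X had 0.375 times the peaks per Mb of the autosomes. A single X per cell was not the whole cause: with the height limit on X set to 1 and on autosomes to 2, the ratio was still 0.576 in replicate 1 and 0.588 in replicate 2. Fewer protein-coding genes per Mb (5.54 against 8.53) were not the whole cause either, since X-linked genes had a promoter peak 0.744 times as often as autosomal genes. A single X together with fewer open genes per Mb, 2.51 against 5.14, may account for it: per open gene and at the halved height limit, X had 1.16 and 1.18 times the promoter peaks of autosomes, but 1.32 and 1.36 times the other peaks, beyond the 1.2 set as the upper bound, and the latter ratio ran from 1.00 and 1.097 to 1.93 and 2.06 as the autosomal height limit rose from 1.5 to 3, so it stays undecided. The count of open genes itself depends on height on X, which limits this test.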

How the results depend on the processing

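The distal definition that excludes start sites of all annotated genes and the promoter definition that asks for 1 region shared by both libraries were chosen after seeing the data. The former gave 6 lists above the limit, and the latter 59.4% of genes with a promoter peak and 5 and 10 lists beyond the limits. Of 410 alternative values 169 moved beyond the replicate spread or by over 1.5 times, and none reversed, where a list counted as reversed only if it went from beyond a limit to the other side of percentile 50. Lists inside the limits moved widely, such as interneuron promoters from 54.6 to 14.2 with peaks above the median height and progenitor distal density from 42.3 to 95.4 with 50 kb flanks. With the shorter peak list, libraries held 41957 peaks on average, 74.96% were shared, rho was 0.939, promoter peaks were 1.86 times as tall as distal ones and the X ratio was 0.373. With peaks above the median height the values were 38062 peaks, 82.5% shared, 53.6% of genes with a promoter peak and an X ratio of 0.220. Overlap of 50% of both intervals gave 57.4% of peaks shared, rho 0.931 and 33.6% of footprints shared. Windows of 500 and 2000 bp gave 31.8% and 39.4% of shared regions at promoters, height ratios of 2.00 and 1.64, and 58.1% and 61.8% of genes with a promoter peak. With 1 start site per gene 28.3% of regions lay at promoters, and promoter peaks per gene gave an X ratio of 0.755. With 50 kb flanks 2 lists, immediate early and astrocyte genes, lay above the distal limit in place of 4. Leaving out each library in turn gave 31.5% to 33.8% of regions at promoters and 61.1% to 62.4% of genes with a promoter peak, since a peak in 1 library then sufficed. For the other moves the cause was not tested. Lists above the promoter limit numbered 4 to 6 and below it 8 to 10 under the alternatives run for them, against 5 and 10, and motifs with a ratio of at least 2 numbered 9 or 10. No paired analysis was possible because there is 1 group. Without read depth, sites under the calling limit cannot be told from closed ones.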

Other observations

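The gene families below and the test of GC content were chosen only after the results were seen. Unlike those for the 22 lists, the random lists for a family could include its own genes. This draws the random median toward the family's own share, most of all for a large family such as the olfactory receptors. Olfactory receptor genes, which are silent in most tissues, seldom had a called promoter peak: 10 of 1135 had one in both libraries (0.881%), against a median of 10.7% in random lists matched on promoter GC content, and 17 had one in 1 library alone. Of 329 vomeronasal receptor genes 1 had one. The clustered protocadherins, from which single neurons are known to express few members each, had few called promoter peaks: 2 of 14 alpha genes (percentile 11.2), 0 of 22 beta genes (percentile 0.16) and 3 of 21 gamma genes (percentile 0.30). Zinc finger protein genes of the Zfp name stood at the other end, with 337 of 394 open (85.5%, percentile 100, random median 58.9%) and median heights of 2.91 and 2.83.

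Glutamate receptor genes had 17 of 24 promoters open (percentile 34.3), GABA-A receptor genes 10 of 13 (percentile 94.8), sodium channel genes 7 of 14 (percentile 31.9) and semaphorins 18 of 20 (percentile 94.8). Keratin genes had 3 of 49 (percentile 0.00) and beta defensin genes 0 of 42 (percentile 0.00). Potassium channel genes had 60 of 92 (65.2%, random median 73.9%), at percentile 2.495 and so just beyond the lower limit, and cadherin genes 15 of 23, at percentile 69.8.

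The peaks called in replicate 2 alone were richer in GC than those of replicate 1 alone, with medians of 54.8% and 50.3%, a gap of 4.53 percentage points (4.32 to 4.88, bootstrap over peaks), and 27.3% against 17.9% of them lay at promoters. In the same order, the medians were 53.6% and 49.3% away from promoters and 59.2% and 57.4% at promoters. A difference in GC content between the libraries was tested as a candidate explanation of the peaks called in 1 library alone and stays undecided, since the gap of 4.53 lay between the bounds of 2 and 5 percentage points.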
